A study of Rattus norvegicus with 14 samples.

How the data were processed

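The submitters processed the reads before the tables used here were made. Their notes name the aligner STAR 2.7.8a, Partek and DESeq2, and the rat build rn7, without saying which tool made which table. The count table holds 18174 genes and 14 libraries, with 1 value for each Ensembl gene and not for each probe, although the assay targets 21119 genes. The estimated counts were made from the reads by the submitters, with a tool that is not stated, and are used as deposited. Of the values 83.6% are whole numbers to a tolerance of 1e-09, and all were rounded before testing. Another table multiplies 16 genes by a factor to undo attenuation, in which the assay lowers the signal of abundant transcripts on purpose. The log2 values of a further table are log2 CPM that the submitters made from the attenuation-adjusted counts of 11624 genes, as deposited, and they were recomputed to within 1e-13. The unadjusted counts were used for testing.

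Genes were filtered with edgeR's filterByExpr on the dose groups, which kept 12719 genes with 99.9% of counts and left out 5455. Of the tested genes 866 have no name in the table. Libraries were scaled by TMM, and 1 quasi-likelihood model with robust dispersion (edgeR 4.0.16, R 4.3.3) was fitted to all 14 libraries, with 9 residual degrees of freedom and a common biological coefficient of variation of 0.232. Each dose was compared with vehicle and with the dose below it. A separate fit gave the slope over dose, as log2 per 100 mg/kg/day. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and all tests were two-sided. Where counts at an unadjusted p under 0.05 are given, a share of 0.05 of the tested genes is expected if no gene differs. Genes vary together, so a share above or below it is not a test. CPM values use the TMM-scaled totals, except those of Afp and of the liver and skeletal muscle genes added later, which use unscaled totals. No paired analysis was possible because the labels give no replicate numbers; replicates are numbered in the order of the labels. The litter is the unit of replication.

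17 gene lists with 269 symbols, of which 44 are absent from the table, were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the 17 lists of a comparison. They were testosterone synthesis, cholesterol synthesis and uptake, other fetal Leydig cell genes, fatty acid synthesis, PPAR targets and fatty acid oxidation, xenobiotic and oxidative stress response, immediate early genes, cell cycle, and markers of Sertoli, germ, peritubular, interstitial, endothelial, macrophage, erythroid, mesonephric and adrenal cells. At 100, 300, 600 and 900 mg/kg/day and over dose, 5, 7, 7, 6 and 7 lists passed, and 3, 4, 5, 4 and 4 passed with an estimated correlation. The fry test, which asks whether the genes of a list move on balance in 1 direction, was passed by 6, 5, 6, 5 and 5 lists.

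The dose at 50% of the vehicle level came from a Hill curve with no floor, fitted by least squares to log2 CPM of 14 libraries, with a 95% interval from the profile of the residual sum of squares. It was fitted for genes of the testosterone, cholesterol and other Leydig lists that fell at 600 or 900 mg/kg/day with an adjusted p under 0.05. An estimate outside 100 to 900 mg/kg/day is given only as outside, below or above that range.

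Genes are named by a rule. For each dose these are the 6 largest rises and the 6 largest falls that passed, with a mean count of at least 20 and every treated litter beyond every vehicle litter, and for the trend the 6 steepest slopes each way. Up to 4 members of each list with the smallest trend p are eligible, and a panel of 14 steroid, sterol and hormone genes is named whatever its values. Symbols that are only identifiers were passed over: 2 falls at 600, 1 rise and 1 fall at 900, and 2 rises and 3 falls in the trend. Cyp11b1 of the panel was not analysed here. Other genes of the lists are named where they passed. Groups, comparisons, lists, thresholds and alternatives were fixed before the data were examined, except the alternatives with surrogate variables and those without vehicle replicate 1 and 100 mg/kg/day replicate 1, which were chosen after seeing the data.

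The methods were first run on counts with known changes, in which 50 genes were shifted at each fold among 12719. The shifted genes had a mean count of at least 20. Genes were simulated independently, so variation shared between genes was absent. With a 1.5-fold shift 12%, 12%, 4% and 20% were recovered at 300, 600 and 900 mg/kg/day and in the trend, with a 2-fold shift 34%, 48%, 46% and 58%, with a 4-fold shift 92%, 98%, 94% and 94%, and with an 8-fold shift 96%, 96%, 96% and 98%. Unchanged genes were called 6, 8, 4 and 10 times. Profile intervals held the true dose in 99.2% of 120 simulated curves. Those curves had no floor, steeper slopes than most fitted genes and less noise than some fits, such as Cyp17a1 (residual SD 0.615). The share thus does not show how well the intervals given here hold. DESeq2 1.42.0 and sva 3.50.0 were used for alternatives, and matplotlib 3.10.9 for the plots.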

Results

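Gene expression was measured in fetal testes from litters of Sprague Dawley rat dams given dicyclohexyl phthalate (DCHP), a plasticizer of the phthalate ester class, by gavage in corn oil from gestational day 14 to 18. Testes were taken on gestational day 18 and pooled within a litter, so each of the 14 libraries stands for 1 litter. There were 3 litters each for the corn oil vehicle, 100, 300 and 600 mg/kg/day, and 2 litters for 900 mg/kg/day. The assay was TempO-Seq, in which pairs of detector probes are ligated on their target RNA and the ligated probes are sequenced. Libraries held 5558873 to 11272861 estimated counts, and 12719 genes were tested. Coordinates are on rn7 as the files give them. Effects are log2 fold changes ± standard error from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p, and levels are CPM, counts scaled to the TMM library size, as mean ± SD over litters.

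The litters did not order by dose along the main axis of variation. On the first principal component, with 33.2% of the variance, vehicle replicate 1 (-43.8) and 100 mg/kg/day replicate 1 (-67.7) lay on the side of both 900 mg/kg/day libraries (-40.2 and -23.5). Vehicle replicate 2 (36.7) and 100 mg/kg/day replicate 2 (39.2) lay at the far end. Correlation of log2 CPM was 0.926 to 0.980 within groups and 0.925 to 0.984 between groups.

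**Figure D1:**
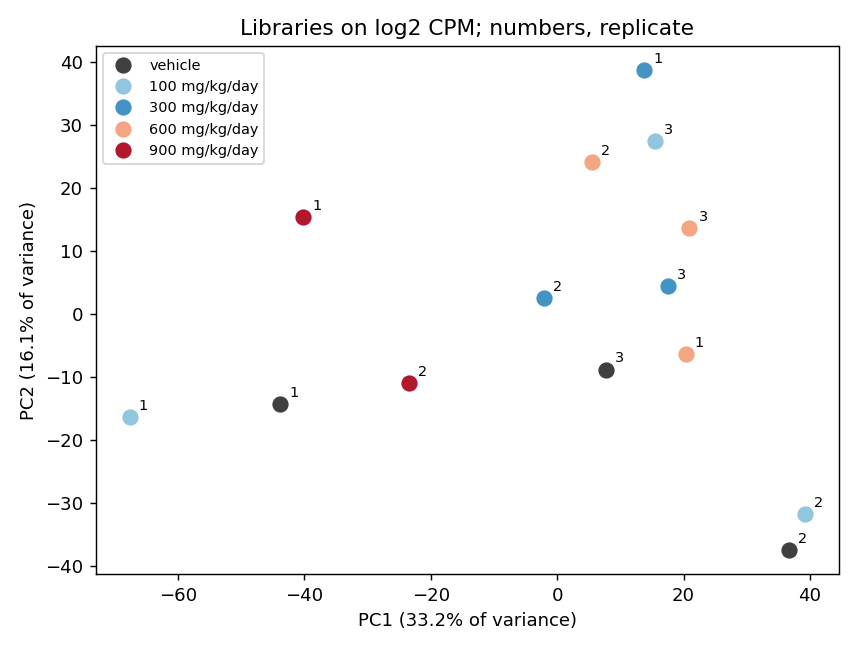
Principal components of log2 CPM over 14 libraries; each point is 1 litter, coloured by dose, with its replicate number. The first component (33.2% of variance) places vehicle replicate 1 and 100 mg/kg/day replicate 1 beside the 900 mg/kg/day libraries.

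The lowest dose was compared with vehicle to ask whether the testis responds at 100 mg/kg/day. No single gene passed in edgeR when adjusted over all genes, while the genes of testosterone synthesis as a group lay lower: 12 of the 13 measured members had a negative log2 fold change. Star, the transporter that brings cholesterol into mitochondria, was at 278 ± 67.3 CPM in vehicle and 126 ± 41.0 CPM at 100 mg/kg/day (n = 3 each), a log2 fold change of -1.15 ± 0.25 with adjusted p = 0.9999 in edgeR. The values of Scarb1, the HDL receptor (-0.84 ± 0.22), Fdx1, the electron donor of mitochondrial P450 enzymes (-0.65 ± 0.20) and Inha, the inhibin alpha subunit (-0.61 ± 0.15) did not pass the test either. The testosterone synthesis list passed limma's camera test as lower (adjusted p = 2.19e-11), and 3 of its members fell when adjusted over the list alone. The other fetal Leydig cell genes also passed as lower (adjusted p = 1.27e-06), with 1 member falling when adjusted over the list alone, as did the PPAR target and fatty acid oxidation list (adjusted p = 0.00292). With an estimated correlation these 3 lists kept their calls at larger camera adjusted p (0.0034, 0.0034 and 0.0291). The cholesterol synthesis list (adjusted p = 2.19e-06) and the fatty acid synthesis list (adjusted p = 0.0334) lost their calls with an estimated correlation (adjusted p = 0.0523 and 0.0835) and passed limma's fry test as lower (adjusted p = 0.0436 each). With edgeR 0 of 12719 genes passed and 433 had an unadjusted p under 0.05, against 2 genes with DESeq2 (432 unadjusted) and 15 or 16 with 1 or 2 surrogate variables added after seeing the data. The 433 genes were 3.40% of those tested, below the share of 0.05 expected if no gene differs. The PPAR list lost its call without vehicle replicate 1 (adjusted p = 0.0830) or without 100 mg/kg/day replicate 1 (adjusted p = 0.0609). The fatty acid list lost its call without vehicle replicate 2 (0.444) or 100 mg/kg/day replicate 1, 2 or 3 (0.111, 0.102 and 0.0942).

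At 300 mg/kg/day 6 genes fell and none rose. They were Svs5, a seminal vesicle secretory protein gene (-2.26 ± 0.33), Star (-1.87 ± 0.25), Scarb1 (-1.58 ± 0.22), Fdx1 (-1.43 ± 0.20), the cell cycle inhibitor Cdkn1c (-1.19 ± 0.18) and Sqle, an enzyme of sterol synthesis (-0.74 ± 0.11). Each had n = 3 litters per group and an edgeR adjusted p between 0.0287 and 0.0293. In the testosterone synthesis list 3 of 13 members fell (7 when adjusted over the list alone; camera adjusted p = 5.55e-26), and Cyp11a1, the side-chain cleavage enzyme, was at -0.99 ± 0.26 (adjusted p = 0.656). In the cholesterol synthesis and uptake list 1 of 17 fell over all genes and 12 when adjusted over the list alone (camera adjusted p = 3.46e-39), and all 17 values were negative. The other fetal Leydig cell genes (adjusted p = 2.70e-07) and fatty acid synthesis genes (adjusted p = 3.86e-06) also passed as lower, with 0 members past the threshold in either list and 1 in each when adjusted over the list alone. With an estimated correlation these 4 lists kept their calls at larger camera adjusted p (0.000115, 0.000137, 0.00172 and 0.00264). The peritubular and smooth muscle markers (adjusted p = 0.00335) and macrophage markers (adjusted p = 0.0436) passed as higher and the PPAR target list as lower (adjusted p = 0.0492), and these 3 lost their calls with an estimated correlation (adjusted p = 0.0881, 0.128 and 0.0943). The peritubular call ended without vehicle replicate 1 (adjusted p = 0.124). The macrophage call ended without any 1 vehicle library, 300 mg/kg/day replicate 1 or 3 or 600 mg/kg/day replicate 1 (adjusted p 0.0502 to 0.193). The PPAR call ended without any 1 vehicle library, 300 mg/kg/day replicate 1 or 2 or any 1 library of 600 mg/kg/day (adjusted p 0.0515 to 0.15). The count of 6 was 0 without vehicle replicate 1 or 3, any 300 mg/kg/day library, 600 mg/kg/day replicate 1 or 2 or either 900 mg/kg/day library (295 to 517 genes at an unadjusted p under 0.05). It was 1 without vehicle replicate 2, 3 without 100 mg/kg/day replicate 3 and 10 without 100 mg/kg/day replicate 1. Each of the 6 calls was lost in 9 to 12 of the 14 fits without 1 library. DESeq2 called 26 genes, among them the same 6, and 40 passed in edgeR without vehicle replicate 1 and 100 mg/kg/day replicate 1, of which 4 were among the 6.

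At 600 mg/kg/day 24 genes fell and 4 rose. Among them were Star (-2.53 ± 0.26), Scarb1 (-2.13 ± 0.23) and Fdx1 (-1.96 ± 0.21), n = 3 litters per group. Cyp11a1 (-1.48 ± 0.26) fell too, with a call that was lost in 11 of the 14 fits without 1 library (highest adjusted p = 0.303). Others were Svs5 (-2.99 ± 0.35), the guanine nucleotide exchange factor gene Arhgef38 (-2.83 ± 0.48) and the stanniocalcin gene Stc2 (-1.72 ± 0.24). Its paralogue Stc1 rose (1.58 ± 0.23, 24.7 ± 4.40 to 73.7 ± 8.40 CPM), as did Testin, a testis protein gene (3.01 ± 0.38), at a mean of 25.4 counts per library. Lrrc39 (3.29 ± 0.60) and Ldb3 (1.74 ± 0.32), the other genes that rose, are named here after their values were seen. Sterol synthesis genes Idi1 (-1.23 ± 0.19), Dhcr7 (-1.02 ± 0.14), Sqle (-0.81 ± 0.11) and Fdft1 (-0.67 ± 0.099) fell, as did Inha (-0.92 ± 0.15) and Hsd3b3, a 3-beta-hydroxysteroid dehydrogenase gene outside the lists and named after its values were seen (-0.97 ± 0.17). Cyp17a1, the enzyme that makes androgens from progestagens, was at -2.14 ± 0.40 (edgeR adjusted p = 0.0584) and Insl3, the Leydig hormone of testis descent, at -1.23 ± 0.39 (adjusted p = 0.681). Of the testosterone synthesis list 4 of 13 fell (7 adjusted over the list alone, camera adjusted p = 5.22e-33). Of the cholesterol list 4 of 17 fell (15 adjusted over the list alone, adjusted p = 4.28e-40), and of the other Leydig list 1 of 9 did (6 adjusted over the list alone, adjusted p = 1.90e-10). The fatty acid synthesis list passed as lower with 0 of 10 members past the threshold and 4 when adjusted over the list alone (adjusted p = 4.69e-05). The PPAR target list passed as lower (adjusted p = 0.00195), with 1 of 18 members, Fabp3, a fatty acid binding protein gene, falling (-0.78 ± 0.14). With an estimated correlation these 5 lists kept their calls at larger camera adjusted p (3.31e-05, 8.19e-05, 0.000402, 0.00555 and 0.0188). Erythroid markers passed as higher (adjusted p = 7.73e-05), and so did the peritubular markers (adjusted p = 0.00175). Neither held with an estimated correlation (adjusted p = 0.335 and 0.0637). The erythroid call ended without 600 mg/kg/day replicate 2 (adjusted p = 0.0962). In that library erythroid markers summed to 34961 CPM, above the other 13 (6197 to 18421 CPM). Of the 28 genes, Svs5, Star, Scarb1, Fdx1, Cdkn1c and Testin kept their call in all 14 fits without 1 library. Sqle, Stc1, Stc2, Dhcr7, Fdft1 and Idi1 lost it in 2 to 6 of them, and Inha, Arhgef38, Hsd3b3, Lrrc39, Fabp3 and Ldb3 in 10 to 12. The count of 28 was 15 with RLE size factors (13 fell, 2 rose), 59 with DESeq2 and 66 without vehicle replicate 1 and 100 mg/kg/day replicate 1. It was 12 and 7 without vehicle replicates 2 and 3, and 50 and 14 without 100 mg/kg/day replicates 1 and 3. It was 12, 13 and 16 without each 300 mg/kg/day library, 11, 7 and 6 without each 600 mg/kg/day library, and 13 without either 900 mg/kg/day library.

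**Figure D2:**
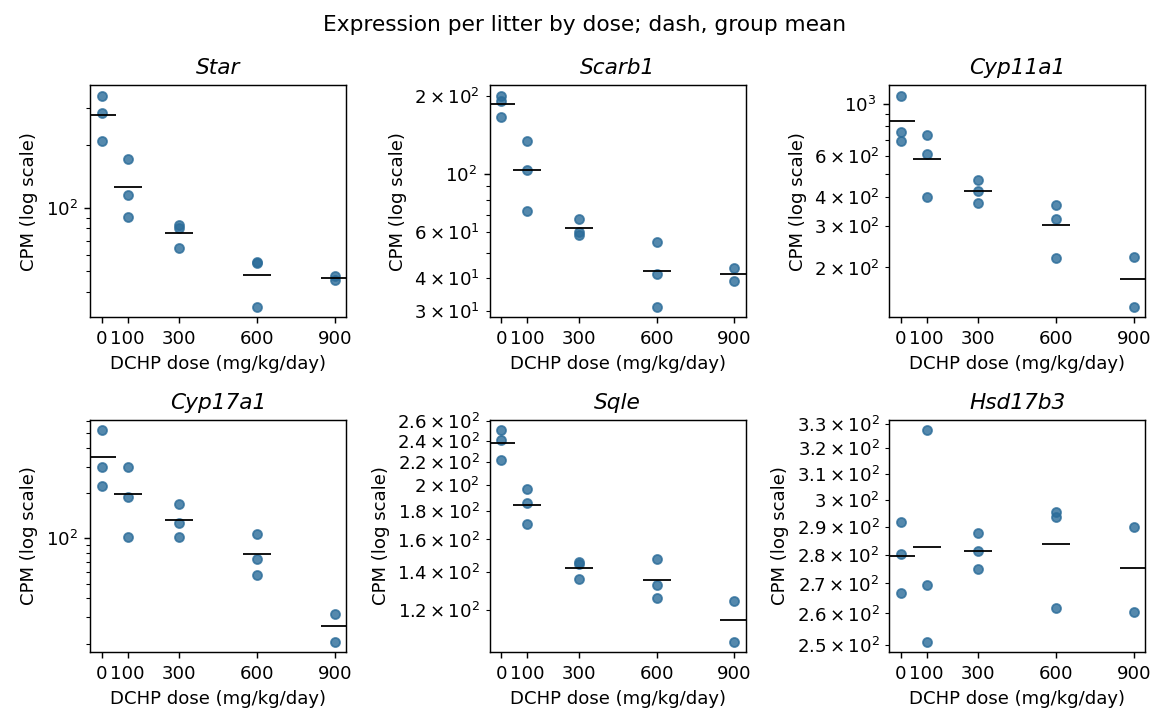
CPM (log axis) against DCHP dose in mg/kg/day for 6 genes; each point is 1 litter and the dash is the group mean. Star, Scarb1, Cyp11a1, Cyp17a1 and Sqle have their lowest group mean at 900 mg/kg/day, while group means of Hsd17b3 lie between 275 and 284 CPM.

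At 900 mg/kg/day 26 genes fell and 6 rose. Svs5 was lowest against vehicle among the named genes (-4.61 ± 0.45, 23.7 ± 5.79 CPM at that dose), followed by Arhgef38 (-4.12 ± 0.61) and Cyp17a1 (-3.74 ± 0.51). Cyp17a1 was at 349 ± 156 CPM in vehicle and 26.1 ± 7.72 CPM at 900 mg/kg/day (n = 3 and 2 litters, edgeR adjusted p = 0.00716). Fdx1 (-2.63 ± 0.25), Star (-2.58 ± 0.30), Cyp11a1 (-2.24 ± 0.31), Scarb1 (-2.17 ± 0.26), Hsd3b3 (-1.42 ± 0.20) and Inha (-1.26 ± 0.17) fell. Genes that rose were Lrrc39 (3.77 ± 0.61), Testin (3.26 ± 0.40), Ldb3, a muscle Z-disc protein gene (1.85 ± 0.34), Stc1 (1.54 ± 0.25) and Cpe, carboxypeptidase E (1.46 ± 0.25), and 1 without a name was passed over. Hsd17b3, the testicular enzyme of the last step to testosterone, was at -0.022 ± 0.12 (0.058 with library totals only) and the Sertoli hormone gene Amh at -0.44 ± 0.29, both without a call. Insl3 (-2.19 ± 0.47, adjusted p = 0.108), Hsd3b1 (-1.42 ± 0.30, adjusted p = 0.105), Lhcgr, the LH receptor (-1.60 ± 0.49), Nr0b1 (-1.41 ± 0.70) and Hmgcs1 (-1.65 ± 0.52) did not pass in edgeR, the last 3 at means of 19.1, 9.29 and 16.7 counts per library. Of the testosterone list 5 of 13 fell (7 adjusted over the list alone, camera adjusted p = 1.70e-28). Of the cholesterol list 6 of 17 fell (14 adjusted over the list alone, adjusted p = 1.95e-40), namely Idi1 (-1.74 ± 0.22), Msmo1 (-1.69 ± 0.30), Sqle (-1.05 ± 0.12), Dhcr7 (-1.01 ± 0.16), Fdft1 (-0.75 ± 0.11) and Stard4 (-0.73 ± 0.13). Of the other Leydig genes 1 of 9 fell (5 adjusted over the list alone, adjusted p = 5.85e-11). The fatty acid synthesis list passed as lower with 0 of 10 past the threshold and 5 adjusted over the list alone (adjusted p = 1.23e-05). With an estimated correlation these 4 lists kept their calls at larger camera adjusted p (8.97e-05, 0.000109, 0.00033 and 0.00367). Adrenal markers, 4 tested and 1 falling when adjusted over the list alone, passed as lower (adjusted p = 0.0116), and so did erythroid markers (adjusted p = 0.0383). Neither held with an estimated correlation (adjusted p = 0.0817 and 0.563). The adrenal call also ended without 900 mg/kg/day replicate 2 (adjusted p = 0.112), and the erythroid call without vehicle replicate 1, 100 mg/kg/day replicate 1 or 900 mg/kg/day replicate 2 (adjusted p = 0.840, 0.0670 and 0.661).

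The count at 900 mg/kg/day rested on few litters. It was 0 without 900 mg/kg/day replicate 1 (335 genes at an unadjusted p under 0.05 in edgeR), 10 without replicate 2, 15 without vehicle replicate 3, 51 without 100 mg/kg/day replicate 1, 5 when only the vehicle and 900 mg/kg/day libraries were fitted, and 86 with DESeq2. Without vehicle replicate 1 and 100 mg/kg/day replicate 1, chosen after seeing the data, it was 2090 genes (942 rose and 1148 fell), among which were all 32. Those 2 libraries lie beside the 900 mg/kg/day libraries on the first principal component. Leaving them out sets that axis along the comparison, so the 2090 genes cannot be read as a response to dose alone. Each of the 32 genes lost its call in at least 1 of the 14 fits without 1 library, and 9 lost it in 8 or more, among them Cpe (8), Ldb3 (11), Stard4 (11) and Msmo1 (12). Fdx1 and Cyp17a1 were among the genes that lost their call without 900 mg/kg/day replicate 1, where the single remaining litter is assumed to vary like the other groups.

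Neighbouring doses were compared to see where along the range expression moves. No gene passed between 100 and 300, 300 and 600, or 600 and 900 mg/kg/day in edgeR, with 312, 161 and 1058 genes at an unadjusted p under 0.05. These were 2.45%, 1.27% and 8.32% of the tested genes. Only the last lay above the share of 0.05 expected if no gene differs. Cyp17a1 at 900 against 600 mg/kg/day was at -1.60 ± 0.47 (adjusted p = 0.508) and Star at 300 against 100 mg/kg/day at -0.72 ± 0.25 (adjusted p = 0.999). DESeq2 called 0, 0 and 8 genes, with 326, 144 and 1201 at an unadjusted p under 0.05. Between 600 and 900 mg/kg/day 2064 genes passed when only those 5 libraries were fitted and 1760 without vehicle replicate 1 and 100 mg/kg/day replicate 1, and between 100 and 300 mg/kg/day 1 gene passed without 100 mg/kg/day replicate 2.

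Across all doses 42 genes fell and 12 rose in a linear trend. Slopes per 100 mg/kg/day were steepest for Svs5 (-0.49 ± 0.042), Arhgef38 (-0.46 ± 0.051), Cyp17a1 (-0.37 ± 0.045), Star (-0.28 ± 0.041), Fdx1 (-0.28 ± 0.026) and Scarb1 (-0.24 ± 0.035) among falls. Among rises they were steepest for Testin (0.34 ± 0.046), Stc1 (0.21 ± 0.032), Cadps, a vesicle secretion factor gene (0.21 ± 0.037), Ldb3 (0.19 ± 0.035), the receptor adaptor gene Grb14 (0.16 ± 0.030) and Cpe (0.13 ± 0.025). In the testosterone synthesis list 6 of 13 genes fell, including Cyp11a1 (-0.23 ± 0.028, edgeR adjusted p = 0.00076) and Hsd3b1 (-0.14 ± 0.028, adjusted p = 0.0433). The call of Hsd3b1 was lost in 13 of the 14 fits without 1 library (highest adjusted p = 0.242). The 22.9 counts per library of Hsd3b1 were not whole numbers in any library, and whether reads are shared with its paralogue Hsd3b3 (-0.14 ± 0.021) was not tested. In the cholesterol list 9 of 17 fell, among them Idi1 (-0.18 ± 0.022), Msmo1 (-0.18 ± 0.027), Sqle (-0.11 ± 0.015), Fdft1 (-0.084 ± 0.012) and Dhcr7 (-0.12 ± 0.020). Hmgcs1, of the same pathway, was at -0.21 ± 0.049 (adjusted p = 0.0845). Of the other fetal Leydig cell genes 2 of 9 fell, Inha (-0.12 ± 0.020) and Insl3 (-0.20 ± 0.042, adjusted p = 0.0466), while Prlr (-0.15 ± 0.039) and Lhcgr (-0.15 ± 0.046) did not pass. The call of Insl3 was lost in 11 of the 14 fits without 1 library (highest adjusted p = 0.252) and that of Inha in 1 (0.0519). In the fatty acid synthesis list 1 of 10 fell, Elovl6, a fatty acid elongase gene (-0.083 ± 0.016), and Fads1 (-0.14 ± 0.031), Scd (-0.29 ± 0.085) and Scd2 (-0.050 ± 0.015) did not pass. The call of Elovl6 was lost in 8 of the 14 fits (highest adjusted p = 0.193). Of the 54 genes 26 kept their call in all 14 fits and 14 lost it in 8 or more. These 4 lists passed camera as lower (adjusted p = 5.26e-32, 4.37e-56, 4.83e-12 and 2.86e-07) and held with an estimated correlation (adjusted p = 0.000191, 0.000191, 0.000791 and 0.00146), with 7, 14, 6 and 4 members falling when adjusted over the list alone.

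**Figure D3:**
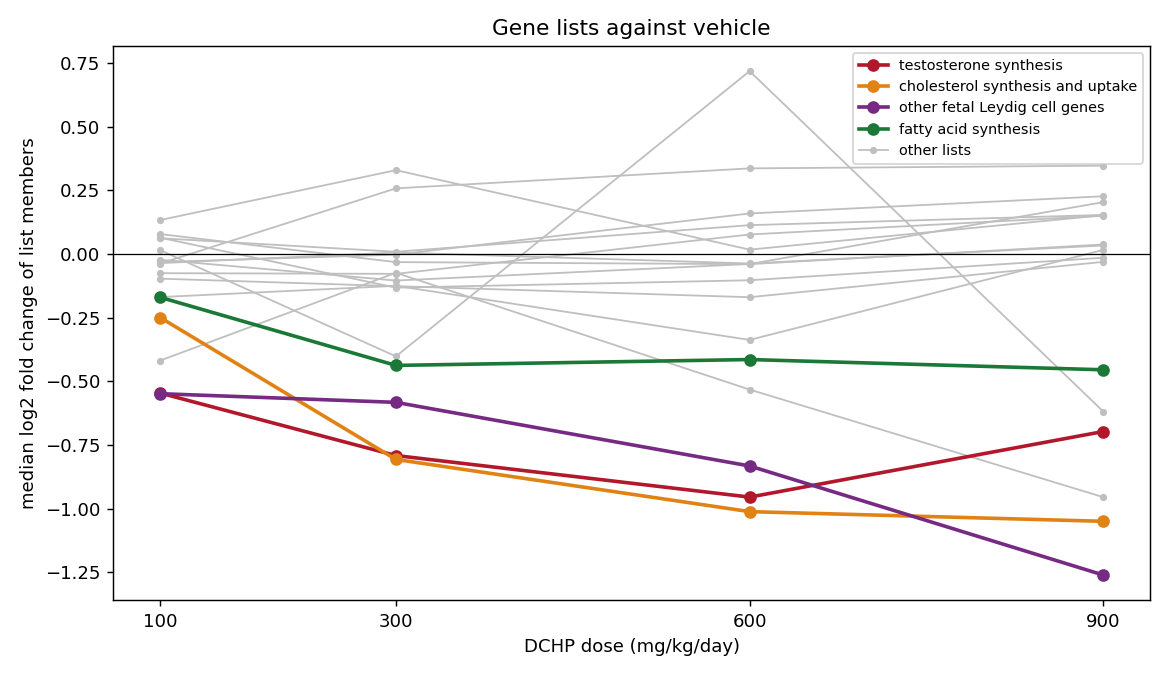
Median log2 fold change of list members against vehicle, by DCHP dose in mg/kg/day; each line is 1 of 17 gene lists. The medians of the cholesterol synthesis list run from -0.25 at 100 to -1.05 at 900 mg/kg/day, and the grey line with the highest value at 600 mg/kg/day is the erythroid list (0.72).

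The remaining 13 lists had 0 members past the threshold over all genes in the trend, and adjusted over the list alone 2 peritubular markers and 1 interstitial marker rose and 2 PPAR targets and 1 adrenal marker fell. Adrenal markers passed as lower (adjusted p = 0.0162, Mrap -0.25 ± 0.060 at 13.6 counts per library). Peritubular markers such as Cnn1 (0.071 ± 0.021) and Acta2 (0.048 ± 0.016) and immediate early genes such as Klf4 (0.066 ± 0.024) passed as higher (adjusted p = 0.00387 and 0.0162). None of these 3 held with an estimated correlation (adjusted p = 0.0753, 0.101 and 0.213). The adrenal call ended without 900 mg/kg/day replicate 1 or 2 (adjusted p = 0.0542 and 0.0662), the peritubular call without vehicle replicate 1 (adjusted p = 0.0682), and the immediate early call without 100 mg/kg/day replicate 2 or 600 mg/kg/day replicate 3 (adjusted p = 0.0621 and 0.0550). With camera no call was made for Sertoli cell markers (Sox9 0.033 ± 0.011, Clu 0.040 ± 0.023, list adjusted p = 0.174), germ cell markers (Sall4 0.066 ± 0.038, adjusted p = 0.379) or interstitial progenitors and fibroblasts (Ptch1 0.041 ± 0.0099, adjusted p = 0.116). Neither was one made for endothelial cells (Tek 0.039 ± 0.017, adjusted p = 0.271), macrophages (Lyz2 -0.038 ± 0.040, adjusted p = 0.412) or erythroid cells (Hbb-b1 0.044 ± 0.057, adjusted p = 0.835). The Sertoli list passed limma's fry test as higher over dose (adjusted p = 0.0496) and as lower at 100 mg/kg/day (adjusted p = 0.0340), and the PPAR list as lower at 900 mg/kg/day (adjusted p = 0.0212), where camera made no call. Fry made none for the peritubular, macrophage, erythroid, adrenal and immediate early lists where camera did at 300 and 900 mg/kg/day and over dose and for the erythroid list at 600 mg/kg/day (adjusted p 0.0522 to 0.524). With camera no call was made either for PPAR targets (Acaa1a -0.064 ± 0.018, Vnn1 -0.064 ± 0.023, adjusted p = 0.104) or xenobiotic and oxidative stress genes (Hmox1 -0.077 ± 0.026, adjusted p = 0.379). Cell cycle genes (Ccna2 -0.053 ± 0.027, adjusted p = 0.546) and mesonephric markers (Lhx1 -0.055 ± 0.030, adjusted p = 0.876) had none. The mesonephric median (0.0091) and mean (-0.0023) differed in sign. The trend count of 54 was 119 with DESeq2, 17 without the 900 mg/kg/day group and 6 without the vehicle group. It was 31 and 34 without 900 mg/kg/day replicates 1 and 2, 35 without vehicle replicate 2 or 3, and 1471 without vehicle replicate 1 and 100 mg/kg/day replicate 1. With those 2 and both 900 mg/kg/day libraries left out it was 40, of which 26 were among the 54.

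Doses at which expression reached 50% of the vehicle level were fitted for 12 genes of the testosterone, cholesterol and other Leydig lists. Scarb1 reached it at 113 mg/kg/day (95% profile interval under 100 to 249), Fdx1 at 182 (under 100 to 319.5), Cyp17a1 at 282 (under 100 to 621) and Cyp11a1 at 319.5 (104 to 609). Among sterol genes Idi1 reached it at 340.1 (168 to 584) and Msmo1 at 446 (190.0 to 798). Dhcr7 reached it at 634 (lower limit 369.6, upper limit above 900) and Sqle at 831 (lower limit 526, upper limit above 900). Inha did so at 621 (lower limit 234, upper limit above 900). The estimate for Star lay below the tested doses, with an upper limit of 175, so its interval overlapped that of Scarb1. Those for Fdft1 and Stard4 lay above the tested doses. The Cyp17a1 estimate was 182 without vehicle replicate 1 and 446 without vehicle replicate 2. That of Scarb1 fell outside the tested doses without vehicle replicate 3 or 100 mg/kg/day replicate 1. That of Sqle fell outside without vehicle replicate 3 or 900 mg/kg/day replicate 1. With a floor in the curve the fitted dose is the midpoint between the vehicle level and the floor, not 50% of the vehicle level. That midpoint lay outside the tested doses for Scarb1 and was 164 and 161 for Sqle and Dhcr7. Intervals of Scarb1 and Sqle did not overlap in the curve without a floor, while those of Cyp11a1 and Idi1 did. The median of the 9 estimates within the tested range was 340.1 mg/kg/day, each fit resting on 14 litters.

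**Figure D4:**
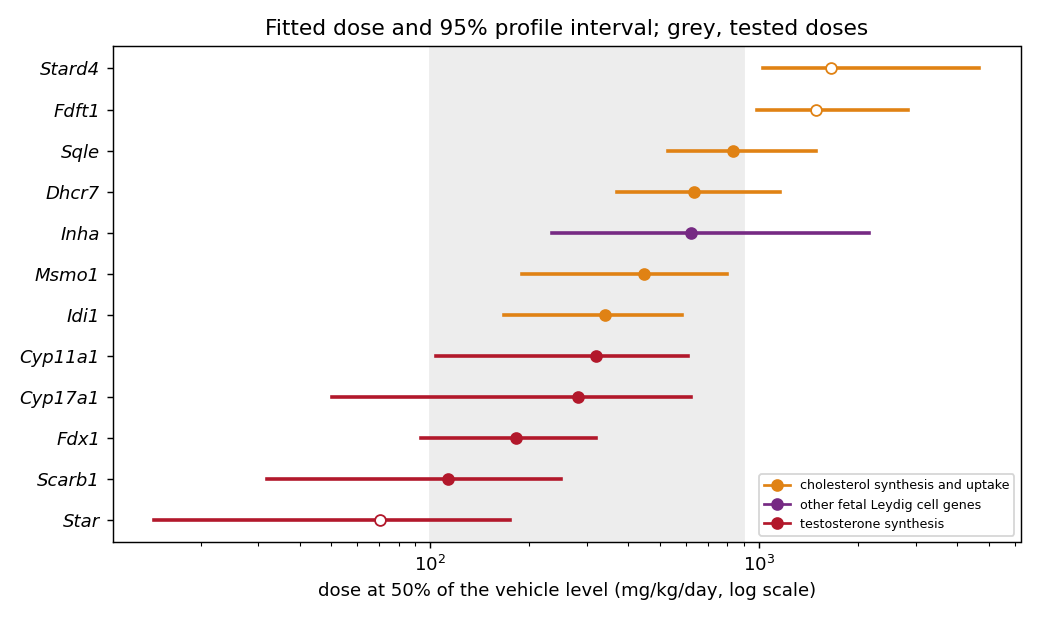
Fitted dose (mg/kg/day, log axis) at 50% of the vehicle level for 12 genes, with 95% profile intervals as lines and colour by gene list; open points lie outside the tested doses, which are shaded. Estimates rise from Scarb1 (113) to Sqle (831) among filled points.

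Calls were shared between doses. Of the 28 genes at 600 and 32 at 900 mg/kg/day, 25 were called in the same direction, 21 falls including Star, Scarb1, Cyp11a1, Idi1 and Dhcr7 and 4 rises including Stc1 and Testin. Independent lists of those sizes would share 0.0491 falling and 0.00189 rising genes, and part of the excess over these may come from the shared controls, since the 3 vehicle libraries are too few to give each dose at least 2 of its own. In 20 simulations of unchanged groups set against shared vehicle libraries 0 genes were shared, which is chance with no effect and does not tell how much the shared controls add here. All 6 genes of 300 mg/kg/day were called at both higher doses. Across genes, which are not independent replicates, log2 fold changes at 600 and 900 mg/kg/day had r = 0.391 against 0.423 simulated, and a covariance of 0.0981 against 0.0822 simulated. At 300 and 600 mg/kg/day r was 0.771 against 0.480 (covariance 0.192 against 0.0832), and at 300 and 900 mg/kg/day 0.464 against 0.438 (covariance 0.119 against 0.0837). For 100 mg/kg/day with 300, 600 and 900 mg/kg/day r was 0.660, 0.540 and 0.568 against 0.490, 0.482 and 0.437 (covariance 0.141, 0.113 and 0.122 against 0.0836, 0.0837 and 0.0837). The simulations gave all libraries the same dispersion for a gene. In the data, scatter between litters, as chi-square per gene over sampling noise, was 18.1 to 75.1 for vehicle pairs. It was 9.10 to 85.7, 6.74 to 9.66, 8.16 to 25.7 and 9.62 for pairs at 100, 300, 600 and 900 mg/kg/day. Values of r or covariance above the simulated ones thus cannot be told apart from a wider spread of the shared vehicle libraries. With DESeq2 the overlap was 45 genes.

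Positions on rn7 of the genes with most weight here are as follows, and probe positions inside a gene were not used here. Star (ENSRNOG00000015052) lies on chromosome 16, 66264807 to 66271673, Scarb1 (ENSRNOG00000000981) on chromosome 12, 31296156 to 31362648, Fdx1 (ENSRNOG00000012123) on chromosome 8, 52268536 to 52287415, Cyp11a1 (ENSRNOG00000008074) on chromosome 8, 58404669 to 58434339 and Cyp17a1 (ENSRNOG00000020035) on chromosome 1, 245535462 to 245541574. Svs5 (ENSRNOG00000013834) lies on chromosome 3, 152996146 to 152997757, Sqle (ENSRNOG00000009550) on chromosome 7, 90868011 to 90883619, Insl3 (ENSRNOG00000068505) on chromosome 16, 18384829 to 18400561, Inha (ENSRNOG00000020097) on chromosome 9, 76993589 to 76997249, Stc1 (ENSRNOG00000015075) on chromosome 15, 44299621 to 44310265 and Testin (ENSRNOG00000018028) on chromosome 17, 3846899 to 3859386.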

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

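The alternatives with surrogate variables and those without vehicle replicate 1 and 100 mg/kg/day replicate 1 were chosen after seeing the data. The falls of Star, Scarb1, Fdx1 and Svs5 at 600 mg/kg/day kept their direction under every alternative run, and Svs5 lost its call in 3 of them. Values of single genes, lists and fitted doses were compared under the alternatives fixed before the data were examined. Of these 4765 held: genes and lists kept their direction and side of the threshold, and fitted doses stayed within their reported interval. Of the others 292 lost a call, 41 gained one, 99 reversed and 4 fitted doses left their interval. Values with no call as reported are among the 4765 and cannot lose one, so these counts do not measure how well calls hold. Under the alternatives added later, in which no doses were fitted, 480 held, 27 lost a call, 54 gained one and 30 reversed. The alternative of counts summed over probes was not run, since the table holds 1 value per gene. Where no cause is given below, the cause was not tested.

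With DESeq2 the counts of called genes were 2, 26, 59 and 86 at 100, 300, 600 and 900 mg/kg/day, 8 between 600 and 900 mg/kg/day and 119 in the trend, and 45 were shared by 600 and 900 mg/kg/day. RLE size factors gave 15 at 600 mg/kg/day. Only the 2 groups compared gave 15 at 600, 5 at 900 and 2064 between 600 and 900 mg/kg/day. The last of these fits leaves out every vehicle, 100 and 300 mg/kg/day library, so it does not isolate any single library. An adjusted p under 0.1, a looser threshold, gave 12 at 300 mg/kg/day and 85 in the trend. The test against a 1.5-fold change, a stricter one, gave 0, 6 and 10 at 300, 600 and 900 mg/kg/day and 11 in the trend. The trend count was 17 without the 900 mg/kg/day group and 6 without the vehicle group, each with fewer libraries. An estimated correlation left 3, 4 and 4 lists at 100 and 300 mg/kg/day and over dose.

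With 1 surrogate variable the counts were 15, 66, 114 and 127 at 100, 300, 600 and 900 mg/kg/day, 1 between 100 and 300 mg/kg/day and 187 in the trend. With 2 they were 16, 26, 65 and 99, and 122 in the trend. Without vehicle replicate 1 and 100 mg/kg/day replicate 1 they were 40, 66 and 2090 at 300, 600 and 900 mg/kg/day, 1760 between 600 and 900 mg/kg/day and 1471 in the trend. With both 900 mg/kg/day libraries also left out they were 40 and 66 at 300 and 600 mg/kg/day. Vehicle replicate 1 and 100 mg/kg/day replicate 1 lie beside the 900 mg/kg/day libraries on the first principal component. Without them the counts of 2090, 1760 and 1471 thus cannot be told apart from that axis.

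Leaving out 1 library at a time gave 0 to 10 genes at 300, 6 to 50 genes at 600, 0 to 51 genes at 900 mg/kg/day, 0 to 1 between 100 and 300 mg/kg/day and 31 to 76 in the trend. The number of lists ranged over 3 to 6, 4 to 7, 6 to 8, 4 to 10 at 100, 300, 600 and 900 mg/kg/day and 6 to 8 over dose. The median dose at 50% of the vehicle level ranged over 288 to 446 mg/kg/day, and was 347 on the linear scale and 340.1 with adjusted counts. With a floor the median was 282, for midpoints between the vehicle level and the floor, which are not doses at 50%. Where 1 of the 900 mg/kg/day libraries is left out, the lone library is assumed to vary like the other groups. Without 900 mg/kg/day replicate 1 the count at 900 was 0 in edgeR, with 335 genes at an unadjusted p under 0.05.

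Reversed values belonged to genes and lists that passed no test as reported. They are log2 fold changes, per 100 mg/kg/day in the trend, and list means, and for lists it is the direction of the camera test that reversed. With RLE size factors reversed values were endothelial markers -0.0066 at 600. With library totals only reversed values were Hsd17b3 -0.0034 at 600, 0.058 at 900, 0.0028 in the trend. With no filter on low counts reversed values were Hsd17b3 -0.024 at 300, -0.0075 at 600, 0.0035 at 900 and Amh -0.010 at 300. With limma-trend on log2 CPM reversed values were Hsd17b3 -0.0074 at 600, 0.060 at 900, 0.0030 in the trend. With 1 surrogate variable reversed values were Cyp1a1 0.0022 in the trend, Th 0.031 in the trend, Hsd17b3 -0.020 at 300, -0.020 at 600, 0.042 at 900, 0.0013 in the trend and Amh -0.057 at 300, -0.036 at 600, 0.0080 in the trend. With 2 surrogate variables reversed values were Cyp1a1 0.020 in the trend, Tie1 0.014 in the trend, Adgre1 -0.0012 in the trend, Hbb-b1 -0.016 in the trend, Hbz -0.0039 in the trend, Amh -0.081 at 300, -0.054 at 600, 0.0081 in the trend and Hsd17b3 0.10 at 900 and 0.0082 in the trend. Without vehicle replicate 1 and 100 mg/kg/day replicate 1 reversed values were Cd68 -0.0030 in the trend, Rhag 0.048 in the trend, Emx2 -0.0023 in the trend and Amh -0.24 at 300 and -0.17 at 600. With those and both 900 mg/kg/day libraries left out reversed values were Rhag 0.19 in the trend, Emx2 -0.025 in the trend, Wfdc2 -0.011 in the trend, Chga 0.014 in the trend and Amh -0.23 at 300 and -0.17 at 600. Over the fits that each left out 1 library, genes with a reversed value had these ranges. At 100 mg/kg/day these were Amh -0.58 to 0.020, Hsd17b3 -0.10 to 0.094 and Nr0b1 -0.62 to 0.062. At 300 mg/kg/day these were Amh -0.23 to 0.36 and Hsd17b3 -0.023 to 0.041. At 600 mg/kg/day these were Amh -0.17 to 0.43 and Hsd17b3 -0.011 to 0.075. At 900 mg/kg/day these were Hsd17b3 -0.14 to 0.040. In the trend these were Bub1 -0.025 to 0.0058, Tie1 -0.047 to 0.0011, Th -0.043 to 0.043, Amh -0.029 to 0.011, Rhag -0.055 to 0.025, Wfdc2 -0.0054 to 0.017, Hsd17b3 -0.0061 to 0.0041, Hbb-b1 -0.020 to 0.099, Hba-a3 -0.00023 to 0.094, Hbz -0.015 to 0.098, Dnmt3l -0.0090 to 0.11, Mcm4 -0.0035 to 0.017, Rhox10 -0.0088 to 0.059 and Emx2 -0.00039 to 0.044. Mean log2 fold changes of lists at 100 mg/kg/day ranged as follows: immediate early genes -0.26 to 0.040, peritubular myoid and smooth muscle markers -0.0027 to 0.25, endothelial markers -0.12 to 0.073, erythroid markers -0.62 to 0.67, xenobiotic and oxidative stress response 0.24 to 0.49 and cell cycle -0.097 to 0.16. Mean log2 fold changes of lists at 300 mg/kg/day ranged as follows: cell cycle -0.11 to 0.055, interstitial progenitor and fibroblast markers -0.17 to 0.11, endothelial markers -0.061 to 0.022, erythroid markers -0.58 to 0.17, germ cell markers -0.091 to 0.078 and xenobiotic and oxidative stress response -0.025 to 0.34. Mean log2 fold changes of lists at 600 mg/kg/day ranged as follows: endothelial markers -0.092 to 0.031 and cell cycle -0.17 to -0.0047. Mean log2 fold changes of lists at 900 mg/kg/day ranged as follows: cell cycle -0.12 to 0.12, mesonephric duct and tubule markers -0.050 to 0.040 and xenobiotic and oxidative stress response -0.16 to 0.26. Mean log2 fold changes of lists in the trend ranged as follows: erythroid markers -0.040 to 0.057 and mesonephric duct and tubule markers -0.0082 to 0.0049.

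At the depth and number of litters used here, which were not varied, small shifts were seldom recovered. With a 1.5-fold shift 12%, 12% and 4% of genes were recovered at 300, 600 and 900 mg/kg/day, against 92%, 98% and 94% with a 4-fold shift. These shares are for simulated genes with a mean count of at least 20, drawn independently. The spread along the first principal component was not simulated, so the shares may be too high for these data.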

Other observations

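The tests of the 900 mg/kg/day dose, of blood, of fewer Leydig cells, of fetal liver and of the second principal component were chosen only after the result was seen. So were the liver and skeletal muscle genes and the libraries named for them, so their counts are descriptions and not tests. No group had 4 or more litters, so no library was tested as lying far from its group.

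Libraries spread along the first principal component in a way that did not follow dose, with vehicle replicate 1 and 100 mg/kg/day replicate 1 beside both 900 mg/kg/day libraries. Argued against as the sole cause was a response to the 900 mg/kg/day dose, since libraries not given it spread more widely along the axis (range 80.5 inside vehicle and 107 inside 100 mg/kg/day) than the 900 mg/kg/day mean lay from the vehicle mean (32.0, ratio 2.51 for the smaller range). A probe-by-probe technical difference between libraries remains a candidate explanation. It was examined not on the axis itself but in the mean log2 difference of replicate 1 from replicates 2 and 3 inside vehicle and 100 mg/kg/day. There, subunits of stable complexes scattered at least as widely as random genes of like abundance, with a median spread ratio of 1.218 (proteasome 1.218 over 26 genes, ribosome 1.53 over 48, respiratory complex I 1.03 over 27). The median differences of their members were 0.0917, -0.264 and -0.250, so part of the difference may be shared within a complex, which the spread does not measure. Blood in the samples cannot be told apart from other sources: in log2 erythroid CPM relative to the median, vehicle replicate 1 (0.764) and 100 mg/kg/day replicate 1 (0.529) lay above and both 900 mg/kg/day libraries (-0.206 and -0.808) below, with an SD inside groups of 0.533, while 600 mg/kg/day replicate 2 had the most (1.69) and lay at 5.45 on the axis, and r with the component was -0.144 over 14 libraries, with a 95% interval too wide to decide (-0.627 to 0.419). The labels give no batch, and part of the genes called at 900 mg/kg/day may belong to this axis, since both of its libraries lie on the same side.

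The Leydig cell genes fell with dose, and fewer Leydig cells with no change per cell would lower them all by the same amount. At 600 and 900 mg/kg/day against vehicle the falls of Star (-2.54), Cyp11a1 (-1.79), Cyp17a1 (-2.73), Insl3 (-1.59) and Lhcgr (-1.19) had an SD of 0.65, with an exact permutation p of 0.0179 over 56 splits of 8 libraries, the smallest they can give. Without the low-count Lhcgr the SD was 0.56 and the exact p 0.0714, while over dose in all 14 libraries the slopes of the other 4 genes had an SD of 0.071 (permutation p = 0.0222, and 0.0551 without 900 mg/kg/day replicate 2). Fewer cells with no change per cell are thus argued against as the sole cause only if no technical difference between libraries follows dose. The argument rests mainly on Cyp17a1, which fell more steeply than Insl3 (-0.16 ± 0.018 per 100 mg/kg/day). Of the other pairs of these 4 genes only Cyp11a1 and Cyp17a1 differed in slope after Holm adjustment (0.13 ± 0.024). The permutation p of the slopes was 0.315 without Cyp17a1 and 0.0702 without Insl3, against 5.0e-05 without Star and 0.032 without Cyp11a1. The result thus needs both Cyp17a1 and Insl3. A loss of cells as part of the cause stays open, and whether probes of abundant genes respond less to a fall was not tested. The slopes were not fitted without both 900 mg/kg/day libraries, which lie on the same side of the first principal component.

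Of 11 liver genes 7 were higher in both replicates 2 and 3 of 100 mg/kg/day than in each of the other 12 libraries, such as Alb with 28 and 22 counts, and 4 were not (Ambp, F2, Fga and Fgb). These counts are unadjusted, and the assay attenuates Alb, Apoa1, Serpina1 and Fga by factors of 4, 9, 3 and 2 in every library. Their counts are thus lower than those the adjustment gives. Afp, abundant in fetal liver, had 12 and 75 counts in these 2 libraries, and the lower CPM of the pair, on unscaled totals, was 0.545 of the median of the other 12. Fetal liver tissue in these samples cannot be told apart from other sources at these low counts, with the libraries on opposite sides.

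Other splits of the 6 libraries of vehicle and 100 mg/kg/day gave up to 2984 genes, with vehicle replicates 1 and 3 and 100 mg/kg/day replicate 1 on 1 side, which points to a structure of the samples. The real split gave 0 genes in edgeR (433 at an unadjusted p under 0.05, 2 adjusted with DESeq2), and 10 of 10 splits gave as many. For 300 mg/kg/day the real split gave 6 genes and the highest other 0, and for 600 mg/kg/day 28 and 0, each real split being the 1 of 10 with as many. Between 100 and 300 and between 300 and 600 mg/kg/day all 10 splits gave 0 genes in edgeR, as did the real one, with 312 and 161 genes at an unadjusted p under 0.05 and 0 with DESeq2. In each of these 5 comparisons 10 splits are too few for a share under 0.05. For the trend, 2 of 100 assignments of the doses, the real one included, gave as many genes as the 54 found. That share makes chance less likely but does not exclude it. The highest other assignment gave 4432 genes, which points to a structure of the samples.

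The second principal component, with 16.1% of the variance, followed the number of olfactory and vomeronasal receptor genes with a count, 91 to 754 of 774 per library. Over 14 libraries Pearson's r was 0.960 (permutation p = 1e-05, the smallest that permutations can give, adjusted 2e-05) and Spearman's rho 0.903 (permutation p = 4e-05, adjusted 4e-05). Without 100 mg/kg/day replicate 2 and 300 mg/kg/day replicate 1 r was 0.941. The number of all genes with a count, 14803 to 17978, followed the component as well (r = 0.947, permutation p = 1e-05, adjusted 2e-05, and rho = 0.921, permutation p = 3e-05, adjusted 4e-05), so receptor genes are not shown to be particular.

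Of 8 skeletal muscle genes 4 (Acta1, Myh3, Mylpf and Tnnc2) were higher in both replicates 1 and 2 of 600 mg/kg/day than in each of the other 12 libraries, and 4 were not. Ldb3, called as higher at 600 mg/kg/day, was at 3.50, 4.66 and 3.70 CPM in replicates 1 to 3 of that dose.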
